A study of Mus musculus with 18 samples.

How the data were processed

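Total RNA from the amygdala of male mice aged 6 weeks was hybridised to Affymetrix mouse exon arrays, 1 array per RNA sample. The 18 arrays fall into 4 groups by genotype and genetic background. Mecp2-null males (n = 4) and wild-type littermates (n = 4) were on the B6 background, and MECP2-transgenic males (n = 5) and wild-type littermates (n = 5) on the FVB background. Per the labels' protocols, the RNA was extracted with TRIzol, treated with DNase, cleaned on RNeasy columns, reverse transcribed and labelled with biotin by in vitro transcription. The arrays are of separate mice per the labels, so the p-values measure the spread between animals.

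The deposited table holds signals for 1201338 exon-level probe sets in each array, and the log2 scale was taken from the values. The submitters' processing notes name GCOS 1.1 and the mm9 build without saying what each was used for. The background correction, normalization and summary method are not given in the sources used here. Deposited values ran from 0.90 to 14.6, and the array medians lay between 4.00 and 4.06. No array pair was near-identical. The mean correlation of an array with the others of its group ran from 0.981 for Mecp2-null replicate 1 to 0.991. For arrays, it is the number of animals that limits the precision. The platform annotation gave 1 gene symbol for 313617 probe sets, several for 7413 and none for 880308. Of 22359 symbols, 18040 were current, 4256 were updated through a RefSeq gene table (GRCm38.p6, used for names alone) and 63 had no match and kept the name on the array. No Mecp2 probe set was analysed here, so the targeted gene does not check the genotype labels.

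Probe sets with a single symbol were kept when their mean over all arrays was at or above the 25th percentile of the table (log2 2.67), and genes when at least 3 such probe sets were left. A Tukey median polish of at most 20 iterations turned 279161 probe sets into values for 18545 genes. The 15939 genes with a mean at or above the 50th percentile of the table (log2 3.99) were tested, with a median of 13 probe sets per gene. Probes that lie over a sequence difference between the strains, and probes shared by paralogs, were not removed.

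All 18 arrays were fitted together in limma 3.58.1 (R 4.3.3, statmod 1.5.0 and version 1.17.8 of data.table) with a mean per group and no covariate, which left 14 residual degrees of freedom. Contrasts were Mecp2-null minus B6 wild type, MECP2-transgenic minus FVB wild type, the difference of these 2 effects, and FVB minus B6 wild type. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 after lmFit and eBayes. The median standard error of a log2 change was 0.113 for Mecp2-null, 0.101 for MECP2-transgenic, 0.151 for the difference and 0.107 for the wild types. Genes called in both genotype contrasts were counted per direction against the count for independent lists, with Fisher's exact test (two-sided). The correlation of the 2 effects was computed across genes, which are not independent replicates.

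Gene lists numbering 28 were fixed before the data were examined, as were the groups, the contrasts, the naming rule and most alternatives. Of these, 27 were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and were adjusted over the lists. The remaining list is the pair of genes that the study followed up. Camera sets a list against all other genes, so its direction can differ from the sign of the list's median. That was so for the glucocorticoid-responsive, MeCP2 target, neurotrophin, Mecp2 neighbour, leptomeningeal and amygdala lists in Mecp2-null. In MECP2-transgenic it was so for the glutamate receptor list, whose mean was positive and median negative. In the difference of effects it was so for the chromatin and neurotrophin lists, and the mean and median also differed in sign for the monoamine and neurotrophin lists. Between the wild types the leptomeningeal list had a negative mean and a positive median. None of these lists passed camera in those contrasts. Exon usage was tested with limma's diffSplice over 258290 probe sets of the same 15939 genes, with Simes adjustment per gene.

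Genes are named by a fixed rule. It takes Crh and Oprm1 in any case, and up to 6 genes with the largest change each way per genotype contrast among called genes with every mutant array on 1 side of the wild-type mean. It adds up to 2 called members per list, genes called in both contrasts, and up to 4 genes each way for the difference and for the wild types. Predicted genes and olfactory receptors were passed over. Other genes are marked as chosen after their values were seen.

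Tests were run on simulated data built on the residual spread of these arrays. In the Mecp2-null design, 50% of changes of 0.5 log2 and 100% of changes of 1 log2 were recovered, with 12 false calls among 15939 genes. In the MECP2-transgenic design, 67% and 97% were recovered with 8 false calls, and between the wild types 65% and 100% with 11. Each design held 100 changes of each size at once, and many calls loosen the adjusted threshold. The real contrasts called 10 genes in Mecp2-null and 77 in MECP2-transgenic, so recovery there is likely lower. Both settings of camera and fry called the list that was shifted and none of the others. The simulated genes varied independently and the lists were random, so this does not check camera where the genes of a list are correlated. For exon usage, diffSplice recovered 181 of 200 changed genes and made 791 false calls. A test of each probe set with its own spread recovered 125 and made 11 false calls. DiffSplice with probe sets weighted by their spread recovered 169 with 219 false calls, and with a trend on the mean 173 with 133. On 200 simulated genes, the median polish missed the true array value with an SD of 0.0779 log2.

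The numbers in the array titles form series, and the labels do not say what these stand for. On B6, series 1592 holds 1 array of each genotype and series 1595 holds 3 of each. On FVB, series 159 holds 2 arrays of each genotype, series 160 holds 1 transgenic and 3 wild-type arrays, and series 165 holds 2 transgenic arrays alone. The series was used as a block in an alternative fit. Further alternatives were each experiment alone, other summaries, filters, scalings, moderation and offsets, array weights, a cortical marker score as covariate, and leaving out each array. Python 3.11.15 and matplotlib 3.10.9 drew the figures.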

Results

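Gene expression in the amygdala of 6-week-old male mice was measured on exon arrays in animals that lack MeCP2 and in animals that carry extra MECP2, each beside wild-type littermates. MeCP2 is a methyl-CpG binding protein whose loss causes Rett syndrome and whose duplication causes a separate neurological disorder. The 4 groups held 4 Mecp2-null arrays, 4 wild-type arrays on the same B6 background, 5 MECP2-transgenic arrays and 5 wild-type arrays on the same FVB background. Values were log2 signals for 15939 genes. Principal component 1 held 36.4% of the variance and component 2 held 15.0%. Mecp2-null replicate 1 stood apart on component 3, with a score of 28.4.

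The first comparison asks which amygdala genes depend on MeCP2, by setting Mecp2-null males against their B6 littermates. Irak1, a kinase of interleukin-1 receptor signalling encoded close to Mecp2 on the X chromosome, rose from 7.13 ± 0.13 to 7.86 ± 0.06 log2 (SD, n = 4 each), or 1.65-fold. Odz3, a teneurin that acts in cell adhesion between neurons, rose by 0.66 ± 0.12 log2 (standard error). Ankrd33b rose by 0.59 ± 0.11. Cd36, a fatty acid transporter and scavenger receptor, fell from 5.13 ± 0.16 to 4.20 ± 0.13 log2 (SD, n = 4 each), 1.90-fold lower. AW551984 fell by 0.87 ± 0.15 and Chrdl1, an antagonist of bone morphogenetic proteins, fell by 0.55 ± 0.10.

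Limma called 10 of the 15939 genes, 3 higher and 7 lower, and 1128 genes had an unadjusted p below 0.05 where chance gives 797. Adjusted p was 0.000752 for Irak1, 0.0112 for Cd36, 0.0292 for AW551984, and 0.0379 for Odz3, Ankrd33b and Chrdl1. The other genes that fell were Gstm6, a glutathione transferase, by 0.67 ± 0.11 (adjusted p = 0.0244), Fgfbp1, a secreted carrier of fibroblast growth factors, by 0.60 ± 0.11 (adjusted p = 0.0379), and Ctxn2, by 0.59 ± 0.11 (adjusted p = 0.0379). C230012O17Rik, passed over by the naming rule and named here after its values were seen, fell by 0.56 (adjusted p = 0.0379). In each of the 9 genes named by rule, all 4 Mecp2-null arrays lay beyond every wild-type array. Fgfbp1 and Ctxn2 rest on 4 probe sets each. The B6 arrays fitted alone gave 2 calls, array weights gave 24 and the title-number series as a block gave 6. Quantile scaling gave 23 calls, 15 higher and 8 lower, and median centring gave 20, 11 higher and 9 lower, so the balance of directions depends on the scaling. Odz3, Ankrd33b, Fgfbp1 and Chrdl1 lost their call under the block. Cd36 lost its call in limma with an offset of 50 (adjusted p = 0.119) and without B6 wild-type replicate 2 (adjusted p = 0.0591). Leaving out B6 wild-type replicate 2 gave 1 call, B6 wild-type replicate 4 gave 2, and Mecp2-null replicates 1, 2, 3 and 4 gave 3, 5, 3 and 4. Through the shared spread, leaving out FVB wild-type replicate 1, 2 or 4 gave 4, 4 and 5, and MECP2-transgenic replicate 1, 2 or 3 gave 6, 3 and 4. All 10 calls had the same sign in the smaller title-number series (1 array of each genotype) and in the larger (3 of each). The genes were called on these same arrays, so the shared sign follows largely from the selection and is not a replication across series.

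Among the lists fixed in advance, markers of the choroid plexus and ependyma passed camera in Mecp2-null, with all 16 measured genes negative and a median of -0.25 log2. None of the 16 passed over all genes, and 4 fell when adjusted over the list alone. These were Kcnj13 (-0.65), F5 (-0.53), Folr1 (-0.52) and Aqp1 (-0.44), genes of the choroid plexus epithelium. Camera gave this list an adjusted p of 1.81e-05, and adjusted p = 0.610 with an estimated correlation. The list's mean score was -0.29 ± 0.20 log2 relative to wild type (SD, n = 4), so the 4 animals varied widely. Neuropeptide genes had a median of -0.15, with 6 of 25 positive, and of -0.05 without Mecp2-null replicate 1 (camera adjusted p = 0.0388). No neuropeptide passed over all genes, and 6 fell when adjusted over the list alone, among them Nts (-0.77), Crh (-0.53), Grp (-0.47) and Oxt (-0.42). Camera gave the neuropeptides an adjusted p of 0.00140, and adjusted p = 0.683 with an estimated correlation.

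Oxidative phosphorylation genes had a median of -0.14 in Mecp2-null, with 6 of 65 positive and none passing over all genes or adjusted over the list alone. The camera adjusted p was 0.000812, and adjusted p = 0.819 with an estimated correlation. Without Mecp2-null replicate 1 the median was -0.01 and the camera adjusted p was 0.793. Microglia markers had a median of -0.18 with 1 of 19 positive, and -0.09 without that array, where the list still passed camera (adjusted p = 0.0383). Their camera adjusted p was 0.00108, and adjusted p = 0.683 with an estimated correlation. Hypothalamic markers had a median of -0.09, and 2 of 17 fell when adjusted over the list alone, Gpr165 (-0.48) and Oxt (-0.42). Camera gave an adjusted p of 0.0154, and adjusted p = 0.683 with an estimated correlation. Without Mecp2-null replicate 3 the camera value was 0.163.

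Lists that camera put higher in Mecp2-null had small medians, and 1 other split of the B6 arrays also gave 12 lists. Presynaptic genes had a median of 0.07, with 23 of 29 positive (adjusted p = 0.000312, and adjusted p = 0.683 with an estimated correlation). Cortical and hippocampal excitatory markers had a median of 0.11, with 14 of 20 positive (adjusted p = 0.000812, and adjusted p = 0.610 with an estimated correlation). Endothelial markers had a median of 0.10 (adjusted p = 0.0267, and adjusted p = 0.809 with an estimated correlation). Glutamate receptor and postsynaptic genes had a median of 0.07 (adjusted p = 0.0129, and adjusted p = 0.809 with an estimated correlation). Chromatin genes had a median of 0.05 (adjusted p = 0.0267, and adjusted p = 0.809 with an estimated correlation). Potassium channels had a median of 0.03 (adjusted p = 0.00846, and adjusted p = 0.736 with an estimated correlation). Immediate early genes had a median of 0.02 (adjusted p = 0.0434, and adjusted p = 0.736 with an estimated correlation). No member of these 7 lists passed over all genes. Adjusted over the list alone, Fosl2 (0.29) and Nptx2 (0.35) rose among the immediate early genes. Without Mecp2-null replicate 1 the endothelial median turned negative (-0.01, camera adjusted p = 0.280), and the glutamate receptor and chromatin medians were 0.01 each (camera adjusted p = 0.769 and 0.285). The presynaptic, potassium channel and immediate early medians were then 0.04, 0.05 and 0.07, and these lists still passed (camera adjusted p = 0.0388, 0.0388 and 0.000725). Striatal markers and GABA signalling passed camera without that array (adjusted p = 0.00224 and 0.0466). It was 0.569 for immediate early genes without B6 wild-type replicate 1, and 0.0834 for potassium channels without B6 wild-type replicate 4.

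The remaining 15 lists did not pass camera in Mecp2-null. Irak1 was the member that rose both among MeCP2 targets reported in other tissues (adjusted p of the list 0.587) and among the X-chromosome neighbours of Mecp2 (0.521). Adjusted over the list alone, Fkbp5 (0.45) rose and Oprk1 (-0.46) fell among the MeCP2 targets. Peptide and steroid receptors had an adjusted p of 0.0831, erythroid markers 0.220, thalamic markers 0.284, GABA signalling 0.323 and striatal markers 0.396. Monoamine and cholinergic genes had 0.482, glucocorticoid-responsive genes, oligodendrocyte markers and astrocyte markers 0.587 each, and neurotrophin and cholesterol genes 0.628 each. Leptomeningeal markers had 0.778 and amygdala nuclei markers 0.851. Camera called 12 of 27 lists, camera with an estimated correlation called 0, fry called 0 for a common direction, and fry called 7 for change in either direction. Adjusted over the list alone, Cckbr (0.39) rose and Oprk1 and Tacr3 (-0.45) fell among the peptide receptors, Fkbp5 and Zbtb16 (0.47) rose among the glucocorticoid-responsive genes, and Htr1a (-0.50) fell among the monoamine genes. In the amygdala nuclei list Dlk1 (0.44) rose and Ecel1 (-0.44) and Gpr101 (-0.38) fell, Calb2 (-0.45) fell in the GABA and thalamic lists, Tnnt1 (-0.34) fell in the thalamic list, and Igfbp2 (-0.53) fell in the neurotrophin and leptomeningeal lists. Gfra1 (0.36) rose in the neurotrophin list.

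The second comparison asks which genes respond to extra MECP2, by setting transgenic males against their FVB littermates. Cd36 rose from 5.36 ± 0.26 to 6.24 ± 0.26 log2 (SD, n = 5 each), or 1.83-fold. Fabp7, the fatty acid binding protein of radial glia and astrocytes, rose by 0.85 ± 0.16 (standard error), and AW551984 rose by 0.77 ± 0.13. Grpr, the gastrin-releasing peptide receptor, rose by 0.78 ± 0.16, the diacylglycerol kinase Dgkk by 0.75 ± 0.11 and the axonemal dynein chain Dnah7b by 0.73 ± 0.08. Ptgs2, the inducible cyclooxygenase, fell by 0.79 ± 0.11, and the heparan sulphate 6-O-sulphotransferase Hs6st3 fell by 0.79 ± 0.12. Zmat4 fell by 0.78 ± 0.10, Adgrl2, a latrophilin, fell by 0.77 ± 0.10, and Odz3 fell by 0.75 ± 0.11.

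Limma called 77 genes in MECP2-transgenic, 33 higher and 44 lower, with changes of 0.33 to 0.87 log2 in size, and 1481 genes had an unadjusted p below 0.05. Adjusted p was 0.000194 for Dnah7b, 0.000507 for Adgrl2, 0.000723 for Ptgs2 and Zmat4, 0.000968 for Dgkk, and 0.00117 for Cd36 and Odz3. It was 0.00183 for Hs6st3, 0.00578 for AW551984, 0.0160 for Fabp7 and 0.0260 for Grpr. All 5 transgenic arrays lay beyond every wild-type array for each of these 11 genes. Grpr rests on 4 probe sets and Fabp7 on 5, and Dnah7b has a paralog, Dnah7a, with which probes may be shared. Quantile scaling gave 176 calls, median centring 162, array weights 225 and an offset of 50 gave 124. With the title-number series as a block 21 genes were called, of which 18 were among the 77, and all 77 kept their sign. Fabp7, Grpr and AW551984 lost their call under the block, and the other 8 of the 11 kept it. Leaving out wild-type replicate 2, 3 or 4 gave 43, 45 and 47 calls, and leaving out MECP2-transgenic replicate 2 or 4 gave 51 and 46. Without the series that holds transgenic arrays alone 25 were called, of which 22 were among the 77. The signs of all 77 were the same in the series with 2 arrays of each genotype and in the series with 1 transgenic and 3 wild-type arrays. Calling the genes on these same arrays favours this, so it is not a replication across series.

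Receptors and signalling genes of the fixed lists were among the 77. With the series as a block Oprk1, Htr1a, Sstr2, Gfra1 and Baiap3 all lost their call. The kappa opioid receptor Oprk1 rose by 0.58 ± 0.13 (adjusted p = 0.0454) and the serotonin receptor Htr1a rose by 0.53 ± 0.10 (adjusted p = 0.00951). The somatostatin receptor Sstr2 fell by 0.47 ± 0.10 (adjusted p = 0.0282) and Gfra1, a receptor for glial cell line-derived neurotrophic factor, fell by 0.46 ± 0.09 (adjusted p = 0.0176). Of 28 peptide and steroid receptors 1 rose and 1 fell over all genes, and adjusted over the list alone Cckbr (-0.40) fell too (camera adjusted p of the list 0.496). Baiap3, a regulator of secretory vesicles, rose by 0.47 ± 0.08 (adjusted p = 0.00772). Its list, hypothalamic markers, had a camera adjusted p of 0.776. The MeCP2 targets reported in other tissues had 1 called member, Oprk1, and 3 of 20 fell when adjusted over the list alone, Fkbp5 (-0.44), Sgk1 (-0.36) and Rbfox1 (-0.30). Their camera adjusted p was 0.248.

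Genes induced by stress hormones and by neuronal activity had negative medians in MECP2-transgenic. Glucocorticoid-responsive genes had a median of -0.22, with 2 of 19 positive. None passed over all genes, and adjusted over the list alone 5 fell, Fkbp5 (-0.44), Cdkn1a (-0.43), Sgk1 (-0.36), Zbtb16 (-0.36) and Errfi1 (-0.22). Camera gave an adjusted p of 1.74e-05, and adjusted p = 0.540 with an estimated correlation. Immediate early genes, which neuronal activity induces, had a median of -0.13, with 4 of 25 positive. Nptx2, a synaptic pentraxin, fell by 0.46 ± 0.09 (adjusted p = 0.0238) and lost its call with the series as a block, and adjusted over the list alone Egr2 (-0.57) and Dusp6 (-0.50) fell too. Camera gave this list an adjusted p of 1.75e-05, and adjusted p = 0.540 with an estimated correlation.

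Markers of neighbouring regions and of other cell types passed camera in MECP2-transgenic as well. Striatal neuron markers had a median of -0.24, with 3 of 16 positive and none passing over all genes or adjusted over the list alone. Their camera adjusted p was 0.000123, and adjusted p = 0.750 with an estimated correlation. Scores of this list varied among the B6 arrays too, with an SD of 0.36 in wild type and 0.38 in Mecp2-null (n = 4 each). Cortical and hippocampal excitatory markers had a median of -0.11, and Lamp5 fell by 0.70 ± 0.12 (adjusted p = 0.00527). Their camera adjusted p was 0.00364, and adjusted p = 0.540 with an estimated correlation. With the score of this list as a covariate, 40 genes were called in MECP2-transgenic, 30 higher and 10 lower, among them 21 of the 33 higher and 8 of the 44 lower calls. That score holds Lamp5, and made without called genes it gave 52 calls, 36 higher and 16 lower, with 39 of the 77 among them. Thalamic markers had a median of -0.13, and Rora fell by 0.43 ± 0.09 (adjusted p = 0.0200), a call lost with the series as a block. Ntng1 (-0.36) fell too when adjusted over the list alone. The camera adjusted p was 0.00364, adjusted p = 0.750 with an estimated correlation, and 0.0874 with the series as a block. Endothelial markers had a median of -0.11 (camera adjusted p 0.00364, adjusted p = 0.750 with an estimated correlation, and 0.233 with the series as a block). Oligodendrocyte markers had a median of -0.12 (camera adjusted p 0.0145, adjusted p = 0.776 with an estimated correlation). With the series as a block camera turned their direction to higher (adjusted p 0.978), and without MECP2-transgenic replicate 4 the value was 0.242. Astrocyte markers had a median of 0.09, with 16 of 19 positive, and Gfap (0.36) rose when adjusted over the list alone. Their camera adjusted p was 0.00522, adjusted p = 0.750 with an estimated correlation, and 0.0608 without MECP2-transgenic replicate 2.

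The other lists did not pass camera in MECP2-transgenic. Chromatin and oxidative phosphorylation genes had an adjusted p of 0.114 each, microglia markers 0.165, and GABA signalling, monoamine genes and the Mecp2 neighbours 0.179 each. Erythroid and leptomeningeal markers had 0.192 each, amygdala nuclei markers 0.238, choroid plexus markers and potassium channels 0.248 each, and neurotrophin genes 0.284. The presynaptic and glutamate receptor lists had 0.407 each, neuropeptides 0.434 and cholesterol genes 0.776. Camera called 8 of 27 lists, camera with an estimated correlation and fry for a common direction called 0 each, and fry called 15 for change in either direction. Adjusted over the list alone, Crh and Nts (0.51) rose and Crhbp (-0.39) and Cck (-0.34) fell among the neuropeptides, Gabra3 (0.29) and Slc6a11 (0.41) rose in the GABA list, and Chrm2 (-0.39) and Htr2a (-0.28) fell in the monoamine list. Kcnj10 (0.35) rose and Kcnab2 (-0.31) fell among the potassium channels, and Plxna3 (0.36) rose among the Mecp2 neighbours. The erythroid list had Hbb-b1 (0.48) higher, and Irs2 (-0.39), Slc4a5 (-0.36) and Dlk1 (-0.34) fell in the neurotrophin, choroid plexus and amygdala lists.

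**Figure D1:**
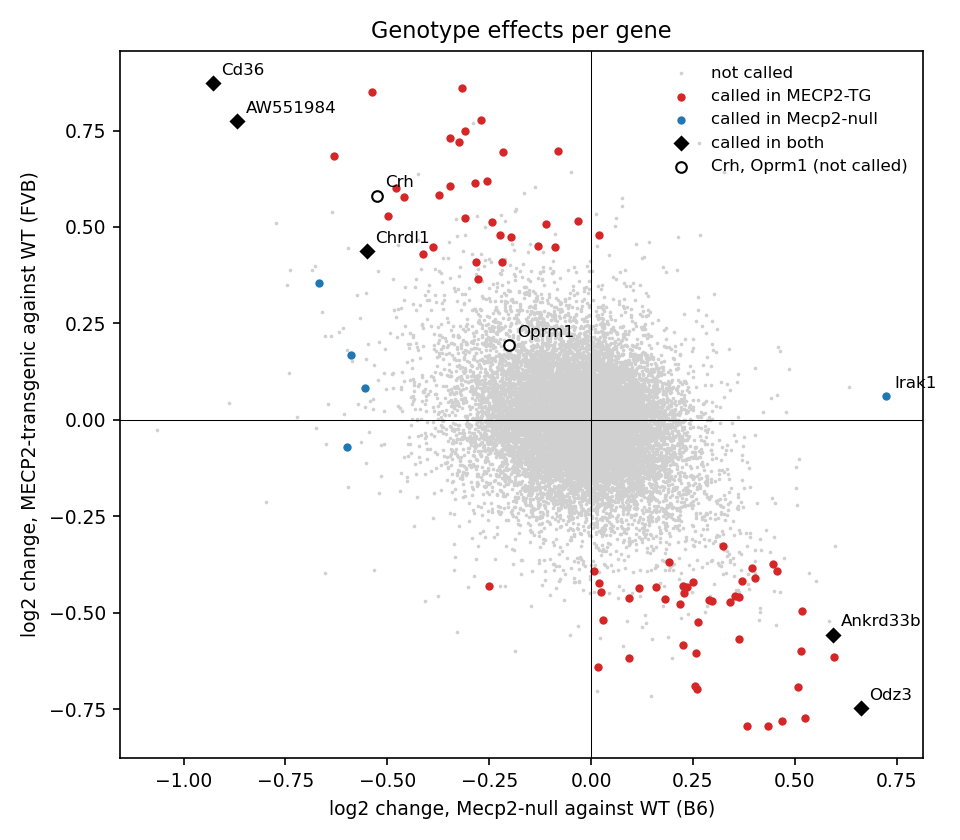
Each point is 1 of 15939 genes, with its log2 change in Mecp2-null against B6 wild type on the x axis and in MECP2-transgenic against FVB wild type on the y axis. Of the 77 genes called in MECP2-transgenic, 75 lie in the quadrants of opposite sign, and the 5 genes called in both (black diamonds) all do.

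The third comparison sets the effects of losing and gaining MeCP2 against each other. The 5 genes called in both contrasts all moved in opposite directions. Cd36, AW551984 and Chrdl1 fell in Mecp2-null and rose in MECP2-transgenic, while Odz3 and Ankrd33b rose in Mecp2-null and fell in MECP2-transgenic. In MECP2-transgenic, Chrdl1 rose by 0.44 ± 0.09 (adjusted p = 0.0255) and Ankrd33b fell by 0.56 ± 0.10 (adjusted p = 0.00810), and both calls were lost with the series as a block. Independent lists would share 0.0145 genes in the first of these directions and 0.00828 in the second (Fisher's exact test, two-sided p = 2.81e-07 and 2.23e-05). They would share 0.0255 genes with the same direction, and 0 were found. Fisher's test takes genes as independent, which they are not, and the 2 contrasts share 1 estimate of each gene's spread. Its p-values therefore do not measure how often chance would give such an overlap. This count of 5 was 1 with each experiment fitted alone, 1 with the series as a block, 16 with array weights, 15 with quantile scaling and 14 with median centring, and it was 0 without B6 wild-type replicate 2. It was 3, 3 and 1 without B6 wild-type replicates 1, 3 and 4, and 2, 1 and 1 without Mecp2-null replicates 1, 3 and 4. It was 2 each without FVB wild-type replicates 1, 2 and 4, and 3, 1 and 2 without MECP2-transgenic replicates 1, 2 and 3.

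Of the 77 genes called in MECP2-transgenic, 75 had the opposite sign in Mecp2-null, 50 of them with an unadjusted p below 0.05. The exceptions were Coch, at -0.25 in Mecp2-null and -0.43 in MECP2-transgenic, and Dnah7a, at 0.02 and 0.48. Both were named after their values were seen. Of the 10 genes called in Mecp2-null, 8 had the opposite sign in MECP2-transgenic. The exceptions were Irak1, at 0.06 ± 0.08 in MECP2-transgenic (adjusted p = 0.915), and Fgfbp1, at -0.07 ± 0.10 (adjusted p = 0.928). Over all 15939 genes, 55.7% had opposite signs, and Pearson's r of the 2 effects was -0.281 and Spearman's rho -0.211. These are correlations across genes, which are not independent replicates.

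The difference of the 2 effects passed for 207 genes, 99 of them higher and 108 lower in MECP2-transgenic relative to Mecp2-null, and 1818 genes had an unadjusted p below 0.05. In 206 of the 207 the effects had opposite signs. Selecting genes on a large difference of the effects favours opposite signs by itself, so this count is not evidence of reciprocity. Of the 207, 67 were also called in MECP2-transgenic, 9 in Mecp2-null and 136 in neither. The largest differences were in Cd36 (1.80 ± 0.19 log2, adjusted p = 5.91e-05), AW551984 (1.64 ± 0.20, adjusted p = 0.000132), Fabp7 (1.39 ± 0.24, adjusted p = 0.00408) and Stc1, the hormone stanniocalcin (1.32 ± 0.18, adjusted p = 0.000391). On the other side they were in Odz3 (-1.41 ± 0.16, adjusted p = 8.42e-05), Adgrl2 (-1.30 ± 0.14, adjusted p = 7.68e-05), Zmat4 (-1.25 ± 0.16, adjusted p = 0.000200) and Hs6st3 (-1.23 ± 0.18, adjusted p = 0.000719). Irak1 differed by -0.66 ± 0.12 (adjusted p = 0.00463). Strain and genotype model change together here, so the difference also holds any effect of background. Of the 207 genes, 73 also differed between the wild types, as did 2794 of all 15939 genes. Both wild-type groups enter both comparisons, which favours this overlap. Quantile scaling gave 395 genes, 146 higher and 249 lower, median centring 378, 145 and 233, and array weights 430. The series as a block gave 130, 77 higher and 53 lower, and the cortical score as covariate gave 98, 77 and 21, so the balance of directions turned. Leaving out B6 wild-type replicate 4 gave 118 genes, and FVB wild-type replicates 2 and 3 gave 137 and 136.

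Among the fixed lists, 2 neuropeptides differed, Nts (1.28, adjusted p = 0.00865) and Crh, and 2 peptide receptors each way. Oprk1 (1.04) and the neurokinin receptor Tacr3 (0.63) were higher in MECP2-transgenic relative to Mecp2-null, and the cholecystokinin receptor Cckbr (-0.79) and Sstr2 (-0.65) lower. Htr1a differed by 1.03 (adjusted p = 0.000553). Adjusted over the list alone, 4 neuropeptides were higher and 1 lower, and 4 peptide receptors were higher and 2 lower. In the glucocorticoid-responsive list Fkbp5 (-0.89) and Zbtb16 (-0.83) differed, and among the immediate early genes Nptx2 (-0.81) and Dusp6 (-0.78). Camera called 10 of 27 lists for the difference. With cortical markers and immediate early genes the adjusted p was 0.000136, with endothelial markers 0.00213, and with glucocorticoid-responsive genes, microglia and striatal markers 0.00251. It was 0.00466 for presynaptic genes, 0.0189 for potassium channels, 0.0433 for astrocyte markers and 0.0463 for choroid plexus markers. No list passed with an estimated correlation, where the lowest adjusted p = 0.479, and fry called 0 for a common direction and 16 for either direction.

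Crh, the corticotropin-releasing hormone, and Oprm1, the mu opioid receptor, are the genes the study followed up. They were chosen on these samples, so their direction here is not independent evidence. Crh was 5.49 ± 0.12 log2 in B6 wild type and 4.96 ± 0.30 in Mecp2-null (SD, n = 4 each), a change of -0.53 ± 0.15 (adjusted p = 0.349). It was 4.99 ± 0.29 in FVB wild type and 5.57 ± 0.21 in MECP2-transgenic (SD, n = 5 each), a change of 0.58 ± 0.14 (adjusted p = 0.0601). Neither change passed, although all 4 Mecp2-null arrays lay below and all 5 transgenic arrays above every wild-type array. The difference of the Crh effects passed, at 1.11 ± 0.21 (adjusted p = 0.00686). The transgenic change of Crh passed in 4 of 13 alternatives, over which its adjusted p ran from 0.00523 to 0.179. Crh rests on 3 probe sets. Oprm1 did not pass in either contrast, at -0.20 ± 0.09 in Mecp2-null (adjusted p = 0.692) and 0.19 ± 0.08 in MECP2-transgenic (adjusted p = 0.440). Its difference of effects was 0.40 ± 0.12 (adjusted p = 0.138).

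**Figure D2:**
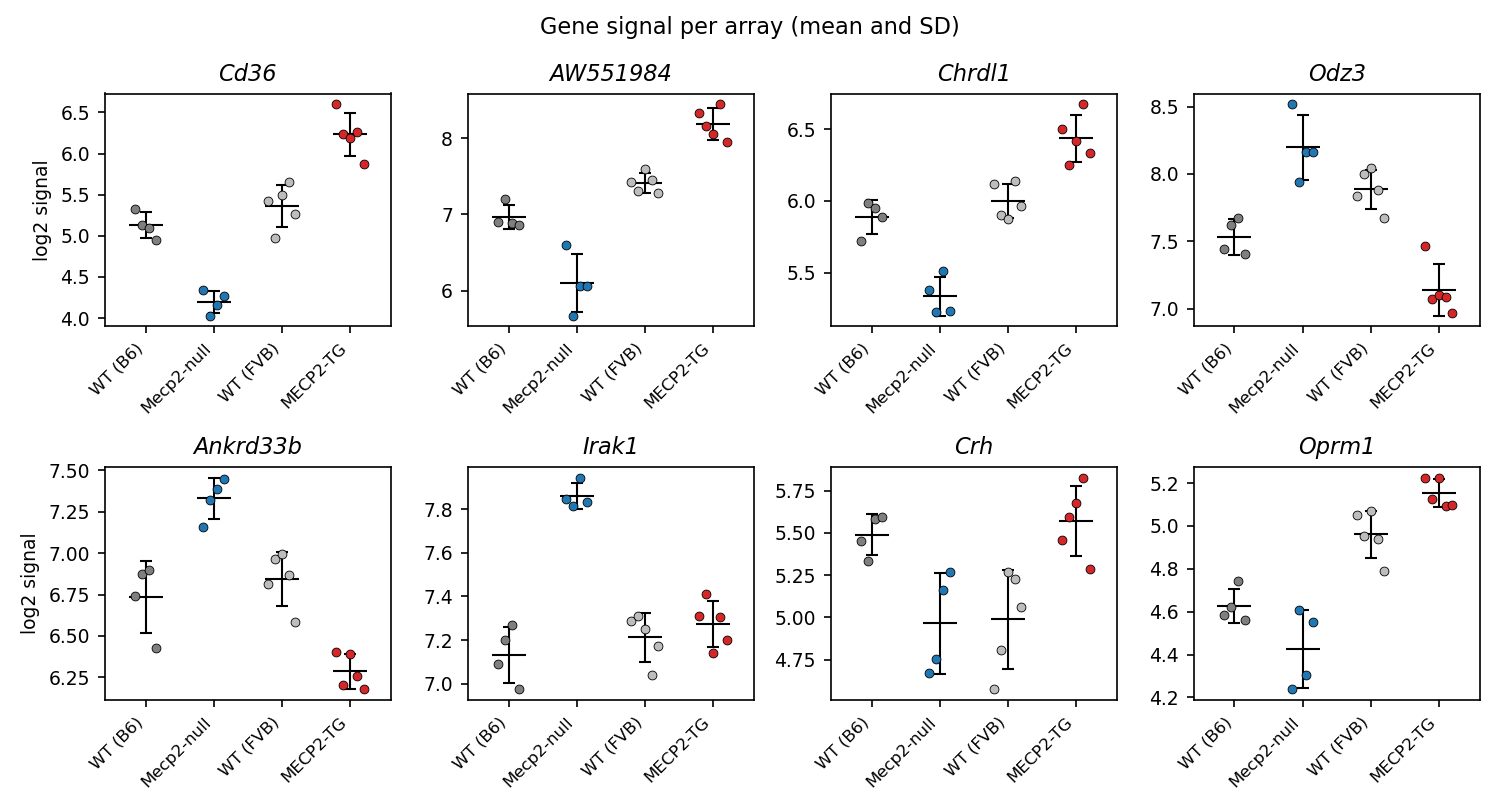
Log2 signal of 8 genes in each array, with the mean and SD of each group (n = 4, 4, 5 and 5). The 5 genes called in both contrasts lie on opposite sides of their wild types, Irak1 stands apart in Mecp2-null at 7.86 ± 0.06, and Crh and Oprm1 show changes that did not pass.

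Exon usage asks whether single exons changed apart from their gene. DiffSplice called 97 genes in Mecp2-null and 121 in MECP2-transgenic, with 3 in both where independent lists would share 0.736. Of these, 0 and 2 were also called by expression, and 1287 and 1543 genes had an unadjusted p below 0.05. With each probe set tested on its own spread, limma called 0 genes in Mecp2-null (589 at an unadjusted p below 0.05, lowest adjusted p = 0.705). The same test called 1 in MECP2-transgenic, Rab11fip1 (adjusted p = 0.0210), whose expression change was -0.08. DiffSplice made 791 false calls on simulated data of this kind, so no gene is named from it.

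The wild-type groups were compared to describe the backgrounds, and 2794 genes differed, 1275 higher and 1519 lower in FVB. Higher in FVB were Gdpd3 (2.71 ± 0.28 log2, standard error), the serine protease inhibitor Serpina3n (2.38 ± 0.24) and the cilia protein Cfap54 (1.51 ± 0.13). Lower in FVB were the beta-globin Hbb-b1 (-3.27 ± 0.17), Pttg1, the securin of cell division (-2.93 ± 0.14), and osteopontin, Spp1 (-2.30 ± 0.17). The naming rule also gave Catspere1, a sperm calcium channel subunit, at 2.73 log2 in B6 and 5.73 in FVB, and Zfp33b, at 5.28 in B6 and 2.97 in FVB. Their lower levels lie below the gene filter of 3.99 and are not shown to be above background, so no size is given. Probes of Hbb-b1 may be shared with its near-identical globin paralogs. Adjusted p was at most 3.58e-06 for these 8 genes. Hybridisation over strain sequence differences, and any batch between the 2 experiments, was not separated from expression. Of the genes called in MECP2-transgenic 25 also differed between the wild types, and of those called in Mecp2-null 5. Each genotype contrast shares a wild-type group with this comparison, which favours such overlap.

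Genes of oxidative phosphorylation were lower in FVB, where 33 of 65 fell and 1 rose, with a median of -0.33 (camera adjusted p = 4.98e-13). Adjusted over the list alone 36 fell and 1 rose. Microglia markers had 9 lower and 2 higher of 19, among them Fcrls (-1.88), C1qc (-1.46) and Aif1 (0.51), with a camera adjusted p of 0.00237. Camera put genes of neuronal signalling higher. Potassium channels had 12 of 42 higher (adjusted p = 2.68e-05), glutamate receptor genes 8 of 34 (7.29e-05), presynaptic genes 6 of 29 (0.000741), peptide receptors 7 of 28 (0.00491), and GABA signalling 10 higher and 1 lower of 27 (0.00519). The monoamine list had 7 of 35 higher, cortical markers 3 higher and 1 lower of 20, and erythroid markers Hbb-b1 lower of 4 measured, with an adjusted p of 0.0245 each. All 10 lists were lost with an estimated correlation, where each had an adjusted p = 0.458 with an estimated correlation, and fry called 11 lists for a common direction. Leaving out B6 wild-type replicate 4 lowered the count of genes to 1685, and leaving out FVB wild-type replicate 3 to 1861.

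**Figure D3:**
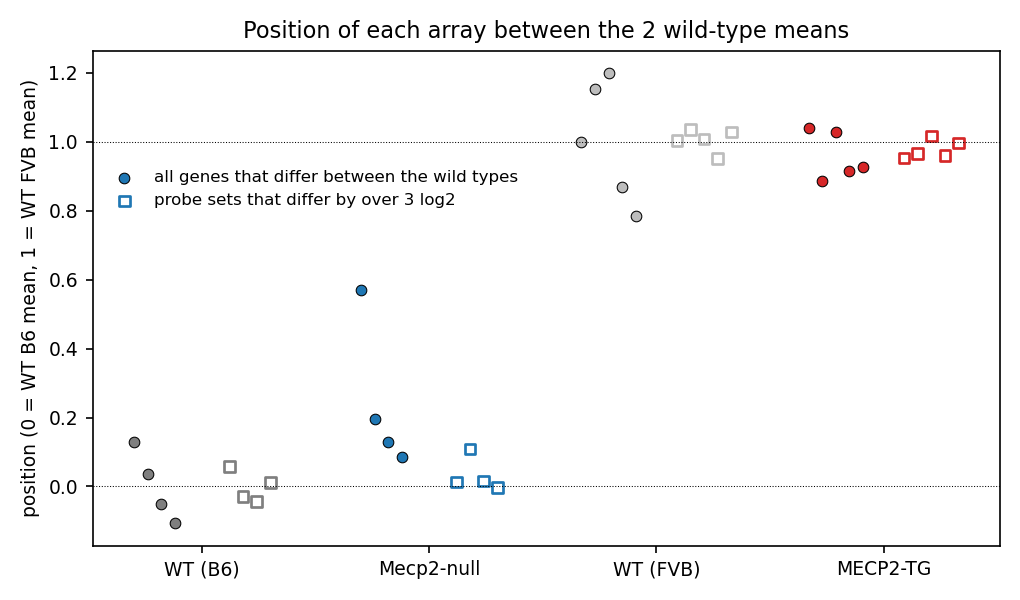
Position of each array between the mean of the B6 wild types (0) and the mean of the FVB wild types (1), as a median over the 2794 genes that differ (filled circles) and over 255 probe sets that differ by more than 3 log2 (open squares). Mecp2-null replicate 1 lies at 0.570 over the genes and at 0.0128 over the probe sets, and the other Mecp2-null arrays at 0.0850 to 0.196 over the genes. Over the probe sets Mecp2-null replicate 2 lies at 0.109.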

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

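Of the tests in this part, the splits of the 8 B6 arrays for the genes called in MECP2-transgenic, the series block and the removal of Mecp2-null replicate 1 were set before their result was seen, and the others were chosen after it. Arrays that lay far from the rest of their group turned up in 6 of 96 groups tested for named genes and 3 of 40 for list scores, where chance gives 4.8 and 2 at 5 percent. The values below are the gap to the nearest array as a share of the group's range.

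AW551984 had its highest B6 wild-type value in replicate 2, at a share of 0.881. Odz3 was highest in MECP2-transgenic replicate 1 (0.732), and Gfra1 in FVB wild-type replicate 2 (0.713) and MECP2-transgenic replicate 1 (0.736). Fabp7 was lowest in B6 wild-type replicate 1 (0.838), at 6.82 log2 against 7.35 to 7.45 in the others. Serpina3n was highest in the same array (0.930), at 8.89 against 7.08 to 7.21. Astrocyte scores were highest in FVB wild-type replicate 1 (0.762) and MECP2-transgenic replicate 2 (0.718). The neuropeptide score was lowest in Mecp2-null replicate 1 (0.924), at -0.41 against -0.11 to -0.09. That array had the lowest array weight, 0.319, beside 0.481 for B6 wild-type replicate 1 and 0.512 for Mecp2-null replicate 2.

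Part of the Mecp2-null list results rested on Mecp2-null replicate 1. Without it the median of the oxidative phosphorylation list kept 5.16% of its size. The microglia median went from -0.18 to -0.09, and that list still passed camera (adjusted p = 0.0383). Over the 2794 genes that differ between the wild types this array lay at 0.570 of the way from B6 to FVB, the other Mecp2-null arrays at 0.0850 to 0.196. Over 255 probe sets that differ by more than 3 log2 it lay at 0.0128, which argues against a swap with an FVB sample. It lay at 0.578 over the 1936 genes that differ by up to 0.5 log2, and at -0.057 over the 10 that differ by more than 2. Over probe sets that differ by more than 1 log2 it lay at 0.260 and Mecp2-null replicate 2 at 0.276. Over the 255 probe sets Mecp2-null replicate 2 lay at 0.109, with 5.10% of them past the midpoint between the wild types. In the other B6 arrays at most 0.784% were past it, and the cause was not tested.

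The difference of the 2 genotype effects passed for 207 genes, and the Crh effects differed by 1.11 log2. Of 100 splits drawn from 8820, 1 gave as many genes, the real split. Another split gave 201, with 3 of 4 Mecp2-null and 3 of 5 transgenic arrays on the wild-type side, so it carries part of both genotype effects in reverse. It also put the 3 B6 arrays of lowest weight on 1 side, and what gave its count was not tested. The remaining splits gave at most 6, and the share excludes chance. For the genes called in Mecp2-null the real split alone gave as many (1 of 35 splits, 10 against at most 3). That is the smallest share these splits can give, and without B6 wild-type replicate 2 the count was 1. Chance was excluded for the genes called in MECP2-transgenic (1 of 100 splits drawn from 126, 77 against 1) and between the wild types (1 of 100, 2794 against 2513). Possible wild-type splits include those with all B6 arrays and 1 FVB array on 1 side, which carry most of the strain difference in reverse. Whether such a split gave 2513 was not examined. Chance was not excluded for the lists in Mecp2-null (2 of 35 splits, 12 against 12), the lists in MECP2-transgenic (21 of 100, 8 against 11), or the correlation across genes (16 of 100, 0.281 in size against 0.449). The genes called in both were 5 in the real split and 0 in the others (1 of 100). Since other splits gave at most 3 calls on B6 and 1 on FVB, a shared gene was hardly possible. This share therefore does not test the overlap. For exon usage, 21 of 35 splits gave as many genes in Mecp2-null (97 against 1873) and 73 of 100 in MECP2-transgenic (121 against 1245). Splits with several times the real count can come from a structure among the arrays or from the test, since diffSplice made 791 false calls on simulated data, and these were not separated.

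Genes called in MECP2-transgenic had the opposite sign in Mecp2-null in 75 of 77 cases, with no array in common between the contrasts. Among the 35 splits of the 8 B6 arrays 1 gave as many, the real split, and the next gave 71, with B6 wild-type replicate 1 and Mecp2-null replicate 1 exchanged, where the mean opposite effect was 0.307 log2 in the real split and at most 0.180 in the others. With the cortical marker score as a covariate the pooled mean kept 96.3%. The 33 genes higher in MECP2-transgenic kept 118% of their opposite effect (32 opposite, 21 still called). The 44 lower genes kept 77.2% (39 opposite, 8 still called). The mean transgenic effect went from 0.59 to 0.67 in the higher genes and from -0.52 to -0.43 in the lower genes. The median standard error of the lower genes went from 0.09 to 0.10. The median over all tested genes also rose in MECP2-transgenic, from -0.0028 to 0.037, and fell in Mecp2-null, from -0.031 to -0.058. The score thus moved both sets of calls alike, so the 118% and 77.2% follow largely from the direction of the calls. Cortex-type tissue stays open for both sets (the score made without called genes kept 39 of the 77 calls in place of 29). With the array series as a block 75 of 77 kept opposite signs. The B6 series hold equal numbers of each genotype, so the block cannot change the size of a Mecp2-null effect. Only a reversed transgenic sign, in genes called on these same arrays, could lower the count, so it does not test the series. Of the calls 53.2% had a Mecp2-null effect with the sign of the strain difference. Between the wild types 32.5% of the calls differed, against 17.5% of other genes. The transgenic and wild-type comparisons share the FVB wild-type arrays, which favours that overlap. A response to MeCP2 level in both directions stays an open hypothesis beside differences in dissection.

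Irak1 rose in Mecp2-null by 0.72 log2 and stood at 0.06 in MECP2-transgenic. A change shared by its neighbourhood is argued against by the other 25 measured neighbours, whose median was -0.0172, between -0.25 and 0.27, with 0 passing in limma. A few faulty probe sets are argued against because 88.5% of the 26 Irak1 probe sets were higher, 18 of them passing when adjusted over the gene alone. An equal and opposite response to MeCP2 dose is argued against by the transgenic change, whose 95% interval ran from -0.103 to 0.224, above the -0.362 that an opposite response of 50% would give. An effect of the modified allele on its direct neighbour may therefore account for the rise, and this was not tested against an effect of MeCP2 loss.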

How the results depend on the processing

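Array weights for single contrasts and for genes called in both, the cortical score as covariate, and the added exon tests were chosen after the data were seen, and the other alternatives before. Genes called in Mecp2-null numbered 10, and 2 with each experiment alone, 24 with array weights, 5 with probe-set means, 4 without the gene filter, 23 with quantile scaling (15 higher, 8 lower), 20 with median centring (11 and 9), 6 with an offset of 50 (4 and 2), 6 with the series as a block (1 and 5) and 3 without the transgenic arrays that form a series alone. The 77 calls in MECP2-transgenic became 225 with array weights, 176 with quantile scaling, 162 with centring, 124 with the offset, 21 with the block, 25 without the transgenic arrays that form a series alone (15 higher, 10 lower) and 40 with the cortical score (30 and 10). The 207 genes whose effects differ became 430 with array weights, 395 with quantile scaling (146 higher, 249 lower), 378 with centring (145 and 233), 130 with the block (77 and 53), 116 without the transgenic arrays that form a series alone, 98 with the cortical score (77 and 21) and 117 with that score made without called genes (85 and 32). The 2794 genes that differ between the wild types became 4488 with array weights. The 5 genes called in both were 1 with each experiment alone, 16 with array weights, 3 with probe-set means, 2 without the gene filter, 15 with quantile scaling, 14 with centring, 8 with trended robust moderation, 3 with the offset, 1 with the block and 2 without the transgenic arrays that form a series alone. In every one of these alternatives and with each array left out, 0 genes were called in both with the same direction. The correlation across genes ran from -0.447 to -0.230, and the share of transgenic calls with the opposite sign in Mecp2-null from 93.3% to 100%. Lists passing camera fell from 12 in Mecp2-null and 8 in MECP2-transgenic to 0 each with an estimated correlation and to 0 each with fry for a common direction, which called 7 and 15 for either direction. Exon usage went from 97 and 121 genes to 20 and 56 with weighted probe sets, 1 and 5 with weights and a trend, and 0 and 1 with each probe set's own spread, where limma had 589 and 823 genes at an unadjusted p below 0.05. The cause of these shifts was not tested.

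With each array left out in turn, Mecp2-null calls ran from 1 (without B6 wild-type replicate 2) to 13 (without B6 wild-type replicate 1), with 2 without B6 wild-type replicate 4, and 3, 5, 3 and 4 without Mecp2-null replicates 1, 2, 3 and 4. FVB arrays share the estimate of the spread, and without single ones of them Mecp2-null calls were as low as 3. MECP2-transgenic calls ran from 43 (without FVB wild-type replicate 2) to 111 (without Mecp2-null replicate 1), the difference from 118 (without B6 wild-type replicate 4) to 211, with 137 and 136 without FVB wild-type replicates 2 and 3, the wild types from 1685 (without B6 wild-type replicate 4) to 3226, and genes called in both from 0 (without B6 wild-type replicate 2) to 5. FVB wild-type replicates 3 and 4 and MECP2-transgenic replicates 2 and 4 each lowered the transgenic calls too, to 45, 47, 51 and 46. The correlation across genes ran from -0.364 to -0.188, the opposite-sign share from 91.0% to 100%, lists in Mecp2-null from 7 (without B6 wild-type replicate 1) to 13, lists in MECP2-transgenic from 7 to 11, exon usage in Mecp2-null from 67 to 410 (without Mecp2-null replicate 1), and in MECP2-transgenic from 110 to 169. Calls that were tested and held in every alternative and with each array left out were 1 of 10 in Mecp2-null (Irak1), 10 of 77 in MECP2-transgenic (Adgrl2, Cacna1g, Cap2, Fgf11, Hs6st3, Odz3, Ptgs2, Rbms3, Zmat4 and Znf41-ps), 33 of 207 for the difference and 1084 of 2794 between the wild types. A gene that a filter left untested in an alternative counts as not held. Cd36, Dgkk and Dnah7b are therefore not among the 10, although in MECP2-transgenic each passed in the 13 alternatives that tested it and in all 18 omissions. The 672 values of named genes under other alternatives gave 576 on the same side of the threshold, 86 no longer past it, 4 newly past it, 6 shifted by more than a standard error without a call, and 0 called values of opposite sign. Crh in MECP2-transgenic accounts for the 4, and its difference of effects passed in all 12 alternatives and 18 omissions. The signs of the medians of all lists that passed camera in a genotype contrast held under both scalings. Only 20 lists were followed through the alternatives, as 100 values, of which 44 no longer passed. The Mecp2 probe sets and the relation to gene length were not run. No paired analysis was possible because the replicate numbers follow the order of the samples and pair no animals. Dim genes are limited by signal over background. The smallest change called was 0.55 log2 in Mecp2-null and 0.33 in MECP2-transgenic. Of simulated changes of 0.5 log2, 50% and 67% were recovered in these designs, where 100 changes of 1 log2 were also present. Those calls loosen the adjusted threshold, and neither genotype contrast had a call over 1 log2. Recovery in the real contrasts is therefore likely lower, and changes of 0.5 log2 and below would often be missed.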

Other observations

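The tests in this part were all chosen after the results were seen. Among the 77 calls in MECP2-transgenic, 6 genes of the motile cilium were picked by eye, from no fixed list and with no test of enrichment among the calls. Dnah7b and Dnah7a, dynein heavy chains, rose by 0.73 and 0.48 log2 (n = 5 each group). The radial spoke gene Rsph4a rose by 0.61 (adjusted p = 0.00391), the central apparatus gene Spag6 by 0.41 (adjusted p = 0.0299), Wdr66 by 0.48 (adjusted p = 0.0265) and Zbbx by 0.60 (adjusted p = 0.0200). In Mecp2-null, 5 of these 6 were negative and none passed in limma, with Zbbx at -0.48, Rsph4a at -0.35, Dnah7b at -0.35, Spag6 at -0.28 and Wdr66 at -0.22, while Dnah7a was at 0.02. For the difference of effects all but Dnah7a (0.46, adjusted p = 0.142) passed, with 1.08 for Dnah7b and Zbbx, 0.95 for Rsph4a, 0.70 for Wdr66 and 0.69 for Spag6.

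A list of 100 genes of the motile axoneme was then written down, of which 68 were measured and 6 called. The 62 called in neither contrast had a median of -0.12 in Mecp2-null, with 55 negative, and of 0.07 in MECP2-transgenic, with 47 positive. All 4 Mecp2-null arrays lay below every B6 wild-type array in the mean of these genes, and 3 of 5 transgenic arrays lay above every FVB wild-type array. The shift in Mecp2-null was 0.130 in size and at most 0.117 in the other splits (1 of 35 as large, the smallest share these splits can give). The list was written after the called genes had been seen to be mostly negative in Mecp2-null, so this shift is a hypothesis from the same data and the splits do not establish it. The shift in MECP2-transgenic was 0.0689, and 9 of 100 splits drawn from 126 were as large, up to 0.107, so chance was not excluded there. Camera gave an unadjusted p of 5.71e-06 in Mecp2-null and 0.000218 in MECP2-transgenic, and p = 0.0245 and p = 0.0592 with an estimated correlation. The medians kept their sign under quantile scaling, centring and each array left out, at -0.14 to -0.10 and 0.05 to 0.08 for the omissions. With the series as a block the transgenic median was 0.06. The block cannot change the Mecp2-null median, as the B6 series hold equal numbers of each genotype.

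More or less ependyma, the ciliated lining of the ventricles, in the dissected tissue may account for this shift. Of 3 ependymal markers outside the list, taken from the marker list fixed in advance, Foxj1 was at -0.24 in Mecp2-null and 0.10 in MECP2-transgenic, Ccdc153 at -0.22 and 0.16, and Tmem212 at -0.24 and 0.03, with none passing. Their median difference of effects was 0.346 log2, more than the 0.177 of the 62 axonemal genes, as such a difference in tissue would give. The whole choroid plexus and ependyma list they come from had a median of -0.08 in MECP2-transgenic with 7 of 16 positive (camera adjusted p = 0.248, towards lower), unlike the 3 markers, and of -0.25 in Mecp2-null with 0 of 16 positive, so the explanation stays open. Foxj1 stood at 5.62 log2 in B6 wild type and 5.38 in Mecp2-null, against 5.21 and 5.31 on FVB, and whether cilia genes respond to MeCP2 within cells was not tested.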
